A study of Mycosarcoma maydis with 2 samples.

How the data were processed

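The study measured messenger RNA of Ustilago maydis FB2 by paired-end Illumina sequencing with 100 nt reads. Per the series' design text, 3 cultures of each condition were pooled before 1 library was made, so the 2 libraries hold no information on the spread between cultures. The groups were taken from the growth condition in the labels: 0.3% ammonium nitrate or none, both at pH 7 in 500 ml of medium shaken at 250 rpm.

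The authors deposited 1 table of raw read counts per gene for each library, per the file headers, with no further normalization. Per the submitters' processing notes, FastQC 0.11.2, BWA, HTSeq and edgeR 3.2.4 were used; their roles and settings, the genome build, the annotation release and the strand setting are not given in the sources used here. BWA aligns without splicing, so reads over exon junctions may be lost if it was used for mapping, in both libraries alike. How reads that map to several places were handled is not stated, so near-identical gene copies remain uncertain. Neither table holds a summary line such as unassigned reads. Both tables list the same 6522 gene identifiers.

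Identifiers (UM followed by 5 digits) were matched to the locus tags of the RefSeq gene table of assembly Umaydis521_2.0 by changing the prefix only. Of the 6522 identifiers, 4652 (71.3%) matched and 1870 did not; matched genes held 70.5% of counts with nitrogen and 73.8% without. The match was checked against gene length: the correlation of log length with log counts was 0.16 for the matched number and between 0.0047 and 0.047 when numbers were displaced by up to 3. The table gives symbols for 15 genes, 12 of them in the files, and no product names. No coordinates are printed, since the build behind the counts is not known.

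Gene lists for 29 pathways and cell functions (nitrogen uptake and assimilation, use of organic nitrogen, transporters, proteases, autophagy, ribosomes, translation, amino acid synthesis, central metabolism, iron uptake, glycolipids, mating, secreted proteins, stress, cell wall and others) were fixed before the data were examined, as patterns on product names and symbols. None of the 29 lists had a member in the files, so none gave a value: the table has no product names, and the genes that 2 lists matched by symbol or gene type (2 amino acid and peptide transporters, 34 mitochondrial genome or ribosomal RNA genes) are not among the matched identifiers. The transporter list, as fixed, did not name opt3, opt4 or opt6. The planned medians of 4 of these lists (inorganic nitrogen, organic nitrogen, amino acid and peptide transporters, cytosolic ribosomal proteins) were therefore not computed. In their place, the 12 genes with a symbol were described in 4 families named by symbol. For genes without a product name the rule fixed beforehand named the 2 with the highest and the 2 with the lowest ratio; other identifiers were chosen after their values were seen.

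Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (1.04 with nitrogen, 0.965 without). TMM-scaled CPM are counts divided by the library total times its factor, times 1e+06. The ratio of a gene is the scaled count without nitrogen over that with nitrogen, with no pseudocount; a count of 0 was set at 3 counts, and a gene with 0 in one library and 3 or fewer in the other was given no ratio. Intervals of ratios are exact (Clopper-Pearson) intervals of the gene's share of the summed counts, rescaled, at a 95% level; reads are not independent molecules, so intervals and the 3-count floor cover counting error only. Genes were described by a rule of size: a ratio of 2-fold or more among genes with at least 50 counts over both libraries. No gene with 50 counts or more was at 0 in either library. edgeR's and DESeq2's tests need replicates and were not run.

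Alternatives were library totals, DESeq2 1.42.0 size factors, upper quartile scaling, totals without the 20 most counted genes of each library (28 genes together), minimum counts of 10, 200 and 1, pseudocounts of 1 count and of 5 CPM, and a whole interval past 2-fold. Centring on a lowess curve (fraction 0.3) was added after seeing the data, as were the runs and the correlations over gene order. Gene order was the order of gene numbers in the files, shuffled 10000 times for runs of 3 or more genes and 1000 times for correlations (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6). The scripts were tested on simulated libraries of this depth with counting error only and 200 altered genes. Of the genes that met the minimum, 99 of 99 altered 3-fold and 97 of 97 altered 8-fold passed the 2-fold rule. So did 2 of 5414 unaltered genes, and 95.5% of intervals held the true ratio. The simulation had no variation between cultures or libraries, so it does not give the rule's error rate in the real data.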

Results

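RNA-seq libraries were made from yeast-like cells of Ustilago maydis strain FB2, a haploid laboratory strain of the corn smut fungus. Cells had been inoculated into minimal medium that contained 0.3% ammonium nitrate or into the same basal medium with no ammonium nitrate. All cultures were shaken at 28 °C for 24 h. Each library pooled 3 cultures, and each condition had 1 library, so the differences below have no replicate check and no p-value is given for any gene. Intervals are 95% counting intervals of these libraries and leave out the variation between cultures. The comparison describes how transcript levels differed between these media at 24 h, the only time sampled. It cannot separate adaptation to the lack of added nitrogen from other differences between the cultures at that time. The library with nitrogen held 3788770 counts and the library without nitrogen 4377669 counts over 6522 gene models. Reads were found for 6314 and 6338 of these models, and the median over all 6522 models was 188 and 190 counts. At these depths a count of 0 allowed a level of up to 0.792 and 0.685 CPM (counts scaled to a library of fixed size), taken as 3 counts.

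Urea transporter genes were higher in the library without ammonium nitrate. The gene dur3-3 (UM04577), which belongs to the DUR3 type of plasma membrane urea transporters, had 113 counts with nitrogen and 1223 counts without. Its scaled level was 10.1-fold higher without nitrogen (counting interval 8.30 to 12.3), at 28.8 and 289.6 TMM-scaled CPM. The gene dur3-1 (UM02625) was 3.41-fold higher (1.90 to 6.50), on 15 and 55 counts. The third member, dur3-2 (UM06253), had 5 and 9 counts, and its ratio of 1.67 had an interval of 0.504 to 6.36 that included no difference. Thus 2 of the 3 family members met the minimum of 50 counts over both libraries, and both were at least 2-fold higher without nitrogen. With a pseudocount of 5 CPM the log2 ratio of dur3-1 was 1.03, against 1.77 without one.

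The 3 oligopeptide transporter genes with a symbol in the files showed no difference beyond counting error. Products of this family carry short peptides into the cell, and any other members could not be identified here. The gene opt6 (UM04347) had 67 counts with nitrogen and 61 without, a ratio of 0.847 with an interval of 0.589 to 1.22. The gene opt3 (UM05968) had 30 and 25 counts, a ratio of 0.775 (0.437 to 1.36). The gene opt4 (UM02387) had 9 and 18 counts, a ratio of 1.86 (0.793 to 4.70), and lay below the minimum of 50 counts. A change of up to the bounds of these intervals was not detectable at this depth.

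Genes for enzymes that act on plant cell wall polymers went both ways. The endoglucanase gene egl3 (UM04816), whose enzyme class cuts cellulose chains internally, was 4.07-fold lower without nitrogen (2.87 to 5.89), on 155 and 41 counts. The endoglucanase gene egl2 (UM02523) was 3.05-fold lower (1.15 to 9.44) on 17 and 6 counts, and egl1 (UM06332) had 1 and 6 counts, a ratio of 5.58 with an interval of 0.677 to 256.6. The gene afu2 (UM00837), named as an arabinofuranosidase, had 3 counts with nitrogen and 84 without, and was 26.0-fold higher without nitrogen (8.61 to 128.8). With so few counts in one library its size depended on the pseudocount: the log2 ratio was 4.70 without one and 2.11 with 5 CPM. The related genes afu1 (UM01829), with 15 and 6 counts, and afu3 (UM04309), with 2 and 4 counts, had intervals that included no difference. Of these 6 genes only egl3 and afu2 met the minimum of 50 counts. These 12 genes were all the gene models in the files with a symbol in the reference table, and they were grouped by symbol after the files were opened but before their counts were compared.

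**Figure D1:**
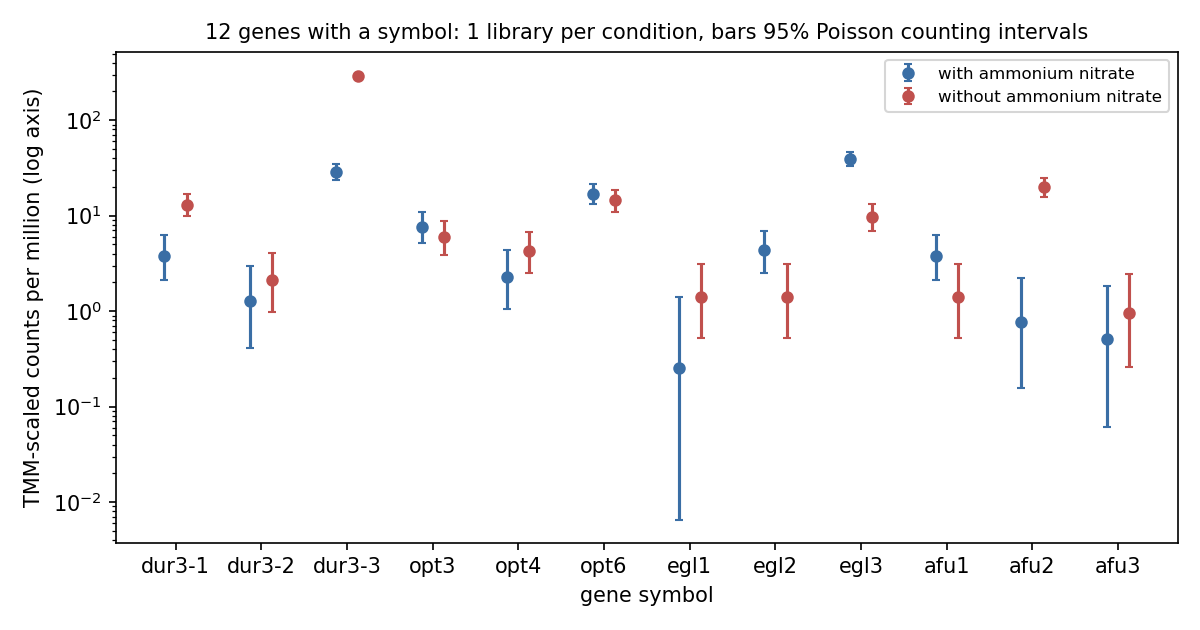
TMM-scaled CPM on a log axis for the 12 genes with a symbol, with ammonium nitrate (blue) and without (red), 1 library each; bars are 95% Poisson counting intervals. The bars are far apart for dur3-3 (28.8 and 289.6), egl3 (39.5 and 9.71) and afu2 (0.764 and 19.9), and overlap for the 3 opt genes.

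With TMM scaling, which left a median log2 ratio of -0.015, differences of 2-fold or more were seen in 1194 genes. They went both ways, and the balance between higher and lower genes depended on the scaling, as given below. Of 5617 genes with at least 50 counts over both libraries, 579 (10.3%) were at least 2-fold higher without nitrogen and 615 (10.9%) were at least 2-fold lower. The remaining 4423 genes (78.7%) lay within 2-fold. At least 4-fold differences were seen for 103 genes that were higher and 76 that were lower, and at least 8-fold differences for 26 and 21 genes. The highest ratio belonged to UM05889, which had 63 counts with nitrogen and 4722 without and was 69.7-fold higher (54.4 to 90.9). The next was UM03849, with 8 and 327 counts, 38.0-fold higher (19.1 to 88.8). At the other end, UM00205 had 2643 and 46 counts and was 61.8-fold lower without nitrogen (46.2 to 84.6), and UM05046, with 106 and 2 counts, was 57.0-fold lower (15.4 to 476.7). With a pseudocount of 5 CPM the log2 ratio of UM03849 was 3.55, against 5.25 without one, and that of UM05046 was -2.55, against -5.83 without one and -5.26 with 1 count. No symbol was paired with these 4 identifiers in the table used here.

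These counts describe size, since 1 library per condition allows no test. The split between higher and lower genes depended on scaling: TMM placed 48.5% of the 2-fold genes on the higher side, DESeq2 size factors 51.0%, upper quartile scaling 43.2%, library totals 38.5%, and totals without the 20 most counted genes of each library 34.1%. Library totals moved the median gene by -0.10 and totals without those genes by -0.14 on the log2 scale. Requiring the whole counting interval to lie past 2-fold left 337 higher and 310 lower genes.

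**Figure D2:**
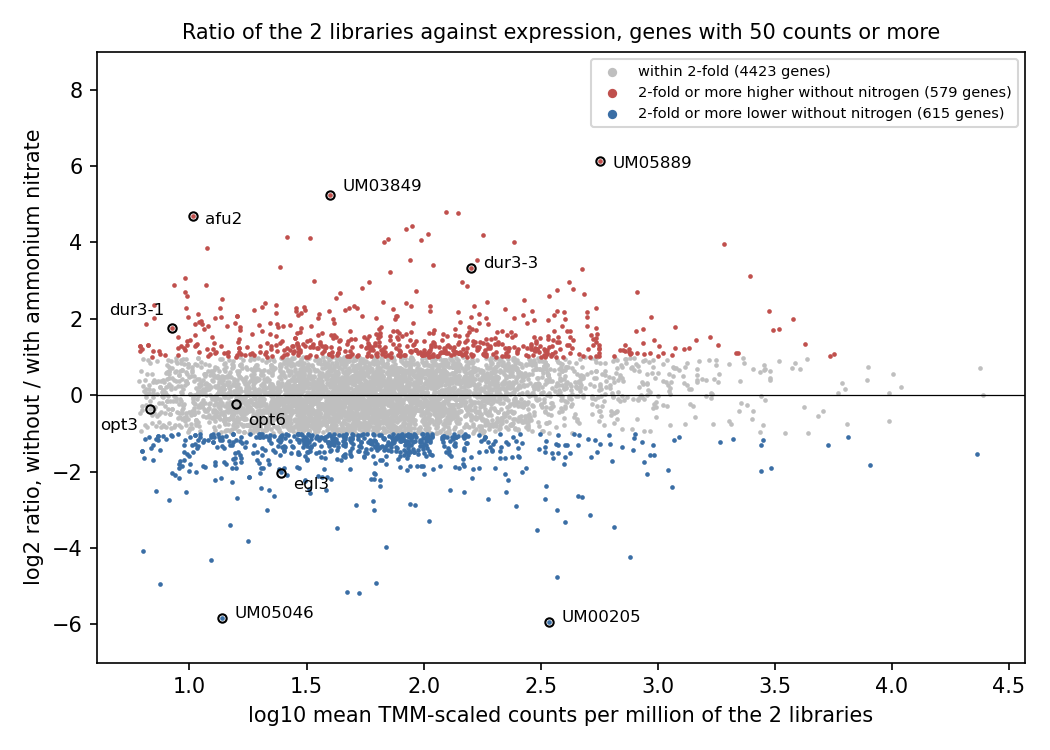
Log2 ratio (without over with ammonium nitrate) against log10 mean TMM-scaled CPM for the 5617 genes with at least 50 counts; red points are the 579 genes at least 2-fold higher without nitrogen, blue points the 615 at least 2-fold lower, grey points the rest, and open circles the named genes. UM05889 lies at the top with a log2 ratio of 6.12, and UM00205 at the bottom with -5.95.

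The most counted genes also differed between conditions. UM06380 took 3.57% of all counts with nitrogen (exact binomial interval 3.55 to 3.58%) and 1.14% without (1.13 to 1.15%), and was 2.91-fold lower on the TMM scale. UM05244 likewise went from 1.30% to 0.342% of counts and was 3.54-fold lower. UM06430 took 1.87% with nitrogen and 2.87% without, a 1.65-fold higher level. UM03881 was nearly level, with 2.52% and 2.36% of counts and a log2 ratio of 0.01 after scaling. The 10 most counted genes of each library took 15.2% of counts with nitrogen and 12.9% without, and 7 genes were among the 10 in both. These 4 genes were chosen from the most counted genes after their values were seen.

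Genes with neighbouring numbers tended to differ in the same direction. Gene numbers stay close to the chromosome order among locus tags of the files' number series. Of successive pairs of such tags on a chromosome of the reference assembly, 97.1% were within 3 numbers of each other. Other locus tags were left out, so genes with such tags may lie between the members of a pair. The 1870 identifiers without a matching locus tag could not be placed in this check. Runs of 3 or more neighbours, each at least 2-fold different in the same direction, numbered 24 and held 81 genes. Of the 24 runs, 13 were higher and 11 lower without nitrogen. Shuffled gene orders held 9.89 runs on average over 10000 shuffles, and 1 shuffle, with 25 runs, held as many or more. The correlation of log2 ratios between adjacent genes was 0.17 across genes, which are not independent replicates, and was -0.0038 at 50 places apart.

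Several of the largest differences lay in such runs, which were picked out after their values were seen. The gene afu2 (UM00837) began a run of 4 higher genes in which UM00838 was 20.3-fold, UM00839 2.89-fold and UM00840 9.84-fold higher. The 4 genes UM03688 to UM03691 were 18.6-fold, 11.5-fold, 18.5-fold and 2.47-fold higher. UM03849 closed a run with UM03847, 4.84-fold higher, and UM03848, 17.7-fold higher. Among lower genes, UM06334, UM06335 and UM06336 were 11.0-fold, 35.3-fold and 3.09-fold lower without nitrogen. A run of 5 genes from UM03173 ended with UM03177, which was 18.7-fold lower on 5683 and 326 counts. Another run of 5, UM01403 to UM01407, was between 2.23-fold and 5.62-fold lower. The counting is not stated to use strand, so reads of overlapping neighbours cannot be told apart.

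**Figure D3:**
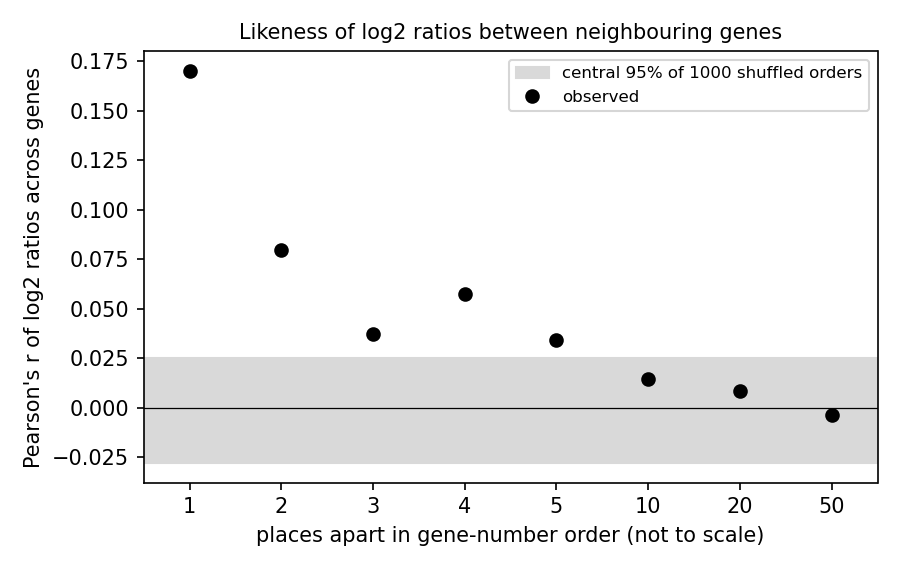
Pearson's r of log2 ratios across genes (vertical axis) between gene models 1 to 50 places apart in gene-number order (horizontal axis, not to scale); the grey band is the central 95% of 1000 shuffled orders. The correlation was 0.17 at 1 place and 0.080 at 2 places. It was 0.037, 0.057 and 0.034 at 3, 4 and 5 places, above the band, and within the band from 10 places on.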

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

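The counts of 2-fold genes stayed within 1.5 times of 579 higher and 615 lower under the other scalings, count minimums and pseudocounts and under lowess centring (419 to 705 higher, 457 to 808 lower). Requiring the whole counting interval past 2-fold moved them to 337 and 310, by its own construction, since genes with few counts have wide intervals. Totals without the most counted genes gave 419 higher and 808 lower genes, and library totals gave 466 and 743. Of 106 values of the 16 named genes under an alternative, 101 stayed inside the gene's counting interval and 0 changed the sign of a 2-fold difference. The other 5 came from a pseudocount of 5 CPM, which lowered the log2 ratio of afu2 from 4.70 to 2.11, of UM05889 from 6.12 to 5.74 and of UM03849 from 5.25 to 3.55, and took UM00205 from -5.95 to -5.41 and UM05046 from -5.83 to -2.55. Under the same pseudocount egl1, egl2 and afu1 stayed inside their wide intervals but fell below 2-fold. Their log2 ratios went from 2.48 to 0.289, from -1.61 to -0.539 and from -1.43 to -0.458. Runs of 3 or more neighbouring genes numbered 23 to 35 under the other scalings. Lowess centring, the pseudocounts for single genes and the settings for runs were chosen after seeing the data. The planned list medians and their percentiles could not be given, since no list had a member. No paired analysis was possible because each condition has 1 library, and for the same reason no library could be left out. Depth limits statements on genes of few counts: dur3-2, opt4, egl1, egl2, afu1 and afu3 had under 50 counts over both libraries.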

Other observations

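Some gene models gave no reads in either medium. Of the 6522 models, 134 had 0 counts in both libraries, 74 had 0 only with nitrogen (at most 18 counts without) and 50 had 0 only without nitrogen (at most 6 counts with). Undetected models lay side by side, for example the 5 models UM01297 to UM01301 and the 4 models UM05092 to UM05095, and 13 of the 30 models from UM05293 to UM05322 had no read. These were chosen after their values were seen. In the tests that follow, those on depth, on gene length over all tested genes and on the neighbours of undetected genes were laid down before their results were seen, and the others after.

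Undetected models formed 34 adjacent pairs, and the 10000 shuffled orders gave at most 10, which argues against chance placement. Of the 134 models with no read, 52 (38.8%) had no matching locus tag in the reference, against 28.7% of all identifiers. A candidate explanation is sequence that FB2 lacks relative to the reference strain, or that reads cannot be placed on uniquely. Detected genes beside an undetected one had a median of 57.5 counts over both libraries, below the 325.0 to 506.0 of random gene sets. Low counts of this kind are also what regions silent in both media would give, so these explanations cannot be told apart: divergent sequence can extend into the neighbours, and the FB2 genome was not used here.

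Neighbouring genes had like log2 ratios, with a correlation of 0.17 at 1 place apart against at most 0.041 in shuffled orders, which argues against a chance order of genes. Reads shared by adjacent gene models could give such a correlation between direct neighbours. The correlation at 2 places, 0.080, exceeded the square of that at 1 place by 0.051 (block bootstrap interval 0.021 to 0.078). Evenly spread sharing would not give such an excess, but sharing confined to some stretches of genes could, so this comparison cannot decide. Shared reads stay open as a cause, in part or in whole. Regulation of groups of neighbouring genes by the nitrogen supply also stays open and was not tested, because each condition has 1 library.

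Abundant genes had higher log2 ratios (without over with nitrogen) than other genes. In the top eighth of genes by expression, 136 of 702 genes were at least 2-fold higher and 72 lower, with a median log2 ratio of 0.34, while in the fourth class of 8 the numbers were 43 and 67 and the median -0.14. The median of the top eighth exceeded that of the rest by 0.40. Its bootstrap interval, 0.32 to 0.48, resampled the genes of these 2 libraries and covers no variation between cultures or libraries. A library's scaling factor, a few genes taking most of its counts or unequal depth could not give this difference, since each moves every gene by 1 expected factor. For that reason thinning the deeper library to the total of the other, which left 0.400, adds no evidence of its own. The length test laid down beforehand required a length for 80% of the tested genes. Only 71.8% of them (4033 genes) had one, so that test gave no decision. In a version set afterwards and limited to these genes, the difference was 0.32 or more within each of 3 equal classes of gene length. Lower interval bounds were 0.17 or more, which argues against length as the whole cause for these genes. For the other genes, with no length given, length stays open. Differences between cultures, between media or in how the 2 libraries were made stay open and are untested with 1 library per condition.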
